A study of Mus musculus with 2 samples.

How the data were processed

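Chromatin immunoprecipitation sequencing for H3K4me1 had been done on 2 pools of forebrain from mouse embryos at day 15.5, of 78 and 62 embryos, with library fragments selected at 300 to 500 bp, per the labels. The labels call the pools biological replicates 1 and 2, and both belong to a single group. The sources for the processing before deposit are the labels and the file listings deposited with the samples. Per these listings, the replicate 1 peaks were derived from that replicate's alignment and 2 further files, and the replicate 2 peaks from its alignment and 1 of those 2 files. These further files were taken to be controls, since the labels name a control experiment. The pooled list was derived from both alignments and both further files, and the replicated list from the pooled list and both replicate lists. The aligner, the peak caller and their versions and settings are not given in the sources used here.

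The 4 deposited lists are in narrowPeak layout on mm10, per the deposited file listings, and the meaning of the columns was taken from that layout. Each peak has a score that the authors scaled within its list, a fold ratio over control that the authors computed, and the deposited -log10 p-value and -log10 q-value of the peak. These values are the authors' and were used to describe, rank or filter peaks within a list. The exception was a comparison of -log10 p between the replicate lists among peaks of similar fold. The smallest deposited -log10 p-value was 2.01 in replicate 1 and 2.02 in replicate 2, and a q-value above 0.05 was carried by 2.54% and 7.08% of the deposited peaks. The lists are therefore permissive, and weak peaks in them carry little evidence by themselves. Read depth was unknown, so the precision of a single peak could not be given. Values per replicate are given as mean ± SD over 2 samples, which describes these samples only.

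Coordinates were checked against the reference sequence of the same assembly (GRCm38), and all peaks ended within their chromosomes. Genes came from GENCODE mouse release M21. Peaks were merged within each list for covered lengths, which used chromosomes 1 to 19, X and Y, as did the gene, location, motif and chromosome comparisons. Peak counts, the shares of peaks found in the other replicate, the deciles and the comparison of the replicated with the pooled list used whole lists, with 6 peaks on other contigs in replicate 1, 2 in replicate 2, 7 in the pooled and 1 in the replicated list. In the shares and deciles these contig peaks counted as not found. A locus was the gene body with 10 kb on each side, clipped at chromosome ends, for the 21911 protein-coding symbols (the longest gene of a repeated symbol). Gene lists were fixed before the data were examined, and all of their members were matched by symbol. Each list's median was compared with 10000 random lists of the same size matched on decile of gene length, and described by its percentile. CpG-rich promoters had a CpG observed to expected ratio of at least 0.6 and a GC fraction of at least 0.5 within 500 bp of the start site, the 5' end of the gene. Chance levels of overlap and of genomic location came from 100 circular shifts of a list within its chromosomes. Location classes were within 1 kb of any annotated start site, then exon, intron and intergenic.

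Motif matches on both strands were counted in distal peaks and in flanking windows of equal length that started 2 kb from the peak and overlapped no peak of the list, and compared with up to 200 rearrangements of each consensus with the same number of CpG. Domains were peaks of the replicated list joined over gaps of up to 1 kb. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. No test across samples was possible with 1 group, and no gene-level p-value was computed.

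The genes named were, for each list, the 3 members with the highest and the 1 or 2 with the lowest mean covered share, a fixed set (Dlx1, Dlx2, Dlx5, Dlx6, Foxg1, Pax6, Emx1, Tbr1, Neurod6, Olig2, Alb, Afp, Actb and Gapdh), the 15 most covered loci, the genes in the 10 widest domains, and the 5 loci with the largest difference between replicates. Where space was short, fewer members of a list were named. Named outside this rule, after their values were seen, were the list genes on chromosome X, the list members Hba-a1, Ahsg and Dppa3, which held no peak, the list member Hba-a2, G430095P16Rik, Tmem249, and the genes named by symbol family or as most covered on chromosome X. Alternatives tried were peaks with a -log10 q of at least 5, equal numbers of top-ranked peaks, overlap of at least 50% of a peak, random placement, other windows around genes and start sites, random lists without length matching, other gaps between joined peaks, flanks that started 10 kb away and leaving out each replicate. Matching on promoter CpG class was added after the data were seen.

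The functions were tested on simulated data before use. In 200 simulated pairs of lists, interval arithmetic differed from base-by-base counts in 0. Of 200 lists of 15 genes drawn at random from the 21911 coding loci, 2.50% lay above and 1.50% below the central 95%. Of lists raised by 2, 5 and 10 percentage points, 10.0%, 56.0% and 99.0% lay above it, so small rises were mostly missed. Motif counts differed from a direct pattern search for 0 of 18 motifs, and a nuclear factor I pair planted in 5 times as many peak as flank windows gave a ratio of 4.75.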

Results

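H3K4me1, the monomethylated form of histone H3 lysine 4 that is found at enhancers and beside active promoters, was measured by chromatin immunoprecipitation sequencing in mouse forebrain at embryonic day 15.5. The series holds 1 group of 2 biological replicates, each a pool of forebrains from embryos of both sexes of the B6NCrl strain: 78 embryos in replicate 1 and 62 in replicate 2. The values used here were peak lists on mm10, with 192719 peaks in replicate 1 and 159735 in replicate 2, a pooled list of 193683 peaks and a replicated list of 127548 peaks. The files held no read counts, so the sequencing depth of each library was unknown. With a single group the design held no comparison between conditions. The comparisons made were between the replicates, between gene groups within the tissue and between the peaks and the rest of the genome, and no p-values were computed, since neither genes nor peaks are replicates.

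The loci of regulators of the developing cortex had the highest median H3K4me1 coverage of the 22 gene lists. For each gene, the share of the locus (gene body and 10 kb on each side) that lay inside peaks was measured. Over 16 regulators of pallial progenitors, the dividing cells of the dorsal forebrain, the median share was 33.8% ± 5.99 (SD, n = 2), against a median of 4.30% for random lists matched on gene length. Sox2, a transcription factor of neural progenitors on chromosome 3 (mm10, 34650405 to 34652461), was covered over 60.4% ± 6.99 of its locus, Hes5, a Notch target that keeps progenitors undifferentiated, over 48.8% ± 2.55, and Emx2, a patterning factor of the dorsal telencephalon, over 42.8% ± 11.8. Pax6 reached 38.2% ± 2.44, Emx1 27.2% ± 3.43 and Foxg1, the forebrain-defining forkhead factor, 17.2% ± 5.91. The lowest members were Foxg1 and Id4, at 13.0% ± 5.03, and none of the 16 lacked peaks.

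Regulators of cortical projection neurons had a median covered share of 21.4% ± 4.36 over 16 genes. Bcl11b, which specifies neurons that project to the spinal cord and lies on chromosome 12 (107910403 to 108003602), was covered over 62.1% ± 5.85 and Neurod2 over 58.6% ± 11.9. Pou3f3 followed with 41.2% ± 11.2. Tbr1, a factor of deep-layer neurons, was covered over 20.5% ± 7.33 and Neurod6 over 10.1% ± 3.75, and the lowest members were Mef2c at 8.46% ± 2.35 and Rorb at 3.72% ± 1.03. Regulators of the subpallium, the ventral source of GABAergic neurons, had a median of 16.9% ± 2.34 over 20 genes. Ascl1, a proneural factor, led with 43.6% ± 5.64, followed by Gsx2 with 36.7% ± 7.19 and Meis2 with 36.3% ± 7.86. The Dlx genes, homeobox genes of GABAergic precursors, reached 24.1% ± 7.96 for Dlx6, 22.8% ± 3.03 for Dlx2, 22.1% ± 5.80 for Dlx1 and 15.3% ± 3.47 for Dlx5. The lowest members were Ebf1 at 7.75% ± 2.11 and Foxp2 at 5.83% ± 1.86. Dlx1 and Dlx2 are neighbours on chromosome 2 and share part of their windows, as Dlx5 and Dlx6 do on chromosome 6.

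In both replicates, the 3 lists lay above the central 95% of 10000 random lists, the smallest of their percentiles being 99.99. Lists of other brain regions and of general functions also lay above that range. Diencephalon regulators had a median of 13.9% ± 1.51, with Barhl2 at 30.3% ± 2.99, Gbx2 at 26.7% ± 2.93 and Irx3 at 23.9% ± 1.91 leading and Six6 at 6.47% ± 1.24 and Sim1 at 3.81% ± 1.00 lowest. Regulators of midbrain, hindbrain and spinal cord had a median of 14.2% ± 2.48, led by Egr2 at 29.0% ± 2.59, Ptf1a at 25.5% ± 2.68 and Mafb at 23.4% ± 1.04, with Pax8 at 4.25% ± 0.298 and Pax3 at 3.1% ± 1.5 lowest. Activity-regulated genes reached 20.3% ± 2.87, led by Junb at 49.5% ± 4.79, Arc at 28.5% ± 4.95 and Fos at 26.7% ± 1.5, and were lowest at Fosl2 with 8.84% ± 2.89. Housekeeping genes reached 17.2% ± 1.79, with Ubc at 30.2% ± 0.616, Actb at 25.9% ± 0.200 and Gapdh at 20.1% ± 1.53, and were lowest at the X-linked Hprt with 0.878% ± 0.354. When random lists were also matched on the CpG class of the promoter, a setting chosen after the data were seen, the diencephalon list fell to percentile 90.4 and the midbrain, hindbrain and spinal cord list to percentile 92.4, both inside the central range. With 50 kb in place of 10 kb on each side of the gene, these 2 lists and the subpallial, the astrocyte and radial glia and the activity-regulated lists lay inside it, the oligodendrocyte list lay above it at percentile 98.3, and 5 lists lay above it in place of 9. With a -log10 q of at least 5 the diencephalon list also lay inside it, at percentile 97.2.

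Among neural cell types, genes of astrocytes and radial glia had a median of 12.7% ± 3.41. Nfix, a nuclear factor I gene, stood highest at 67.3% ± 7.71, followed by Nes, an intermediate filament gene of radial glia, at 39.1% ± 3.70. The related genes Nfib and Nfia, which act in glial differentiation, reached 31.9% ± 7.22 and 29.1% ± 6.17. At the other end, Tnc stood at 2.77% ± 0.837 and S100b, a marker of mature astrocytes, held no peak in its locus. Pan-neuronal genes had a median of 10.5% ± 3.25, led by Tubb3 at 19.1% ± 3.56, Rbfox3 at 17.7% ± 3.24 and Map2 at 16.9% ± 5.54, with Syt1 at 3.52% ± 1.95 and Nrxn1 at 3.01% ± 1.42 lowest. Both lists lay above the central range of random lists, but the pan-neuronal list stood at percentile 84.1 when only 5 kb on each side of the start site was used. Oligodendrocyte lineage genes had a median of 7.65% ± 1.40, inside the range of random lists at percentile 82.0 in replicate 1 and 82.2 in replicate 2. In that list Olig2, also a progenitor factor of the ventral forebrain, was covered over 35.7% ± 2.85 and Olig1 over 15.9% ± 1.43, while Mag, a myelin gene, stood at 2.63% ± 0.0852 and Plp1, an X-linked myelin gene, held no peak.

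Markers of the non-neural cells that a dissected forebrain holds had medians inside the central 95% of random lists. The median was 2.98% ± 0.0866 for microglia and macrophage genes, 3.28% ± 0.540 for endothelial genes, 5.35% ± 1.75 for pericyte and meningeal genes, 4.76% ± 0.598 for choroid plexus and ependymal genes and 2.56% ± 1.68 for erythroid genes. Each list held members well above its median, such as Cd68 at 24.6% ± 4.35, Sox18 at 19.5% ± 2.12, Foxc1 at 22.8% ± 3.12, Foxj1 at 28.7% ± 1.58 and Klf1 at 18.2% ± 0.281. The windows reach beyond each gene, so these shares can include sequence of neighbouring genes, which was not separated here. Other members held no peak in either replicate: the microglial gene Fcrls, the endothelial receptor gene Tie1, the meningeal gene Ogn, and in the erythroid list the globin genes Hba-a1, Hbb-bs and Hbb-bt and the X-linked Gata1 and Alas2. The globin gene Hba-a2 did hold a peak, at 3.84% ± 3.12. The choroid plexus gene Folr1 stood at 0.293% ± 0.414. This held for all 5 lists in both replicates, with percentiles between 17.8 and 69.9.

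Genes of liver and of the germline had the lowest medians among the lists of up to 26 genes. Liver genes had a median of 1.27% ± 1.13 against 4.86% for random lists, at percentile 5.62 in replicate 1, inside the central 95%, and 1.31 in replicate 2, below it. None of the 16 had a CpG-rich promoter, and among random lists also matched on promoter CpG class the list stood at percentile 37.6. Alb and Afp, the genes of serum albumin and alpha-fetoprotein, held no peak within their loci in either replicate, nor did Ahsg and Serpina1b. Foxa3, at 21.5% ± 1.07, was the highest member of that list. Genes of pluripotency and the germline had a median of 1.15% ± 0.0211, inside the range at percentile 2.62 in replicate 1 and 4.81 in replicate 2, with Pou5f1 at 12% ± 1.34 and Prdm14 at 10.2% ± 0.132 highest and Dppa3, Tex101 and Zfp42 without a peak. Heart and skeletal muscle genes had a median of 4.34% ± 1.04, with Hand2 at 16.2% ± 0.730 highest and Nppb without a peak. Hox genes, which pattern the body behind the forebrain, had a median of 6.17% ± 0.572 and lay inside the range of random lists. Hoxd8 was highest at 14.0% ± 0.764, Hoxb13 stood at 0.893% ± 0.131 and Hoxb1 held no peak. The Hox genes lie in clusters, so their windows overlap.

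Most chemosensory receptor genes held no peak. Of 1134 olfactory receptor genes, 1068 held no peak within their loci in either replicate, and of 330 vomeronasal receptor genes, 321 held none. The medians of both families were 0, below all random lists, whose central ranges began at 3.96% and 3.75%. Their highest members were Olfr750 at 8.63% ± 1.20 and Vmn1r4 at 3.63% ± 2.58. With random lists matched on promoter CpG class as well as length, the olfactory family stood at percentile 38.7. The vomeronasal family stayed below all of its random lists. No olfactory gene had a CpG-rich promoter, and these random lists were drawn from genes that include the olfactory genes themselves. The median of the random lists for that family was also 0. Percentile 38.7 therefore cannot tell whether promoter class accounts for the missing peaks. Of 57 keratin-associated protein genes, 36 held no peak, and the highest was Krtap17-1 at 6.01% ± 1.88. Their median of 0 lay inside the central 95% of random lists at percentile 18.2, and below it with 50 kb on each side of the gene, at percentile 1.13, and with random lists not matched on length, at percentile 0. Across all 21911 protein-coding genes the median covered share was 4.66%, and 4716 genes held no peak in either replicate.

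**Figure D1:**
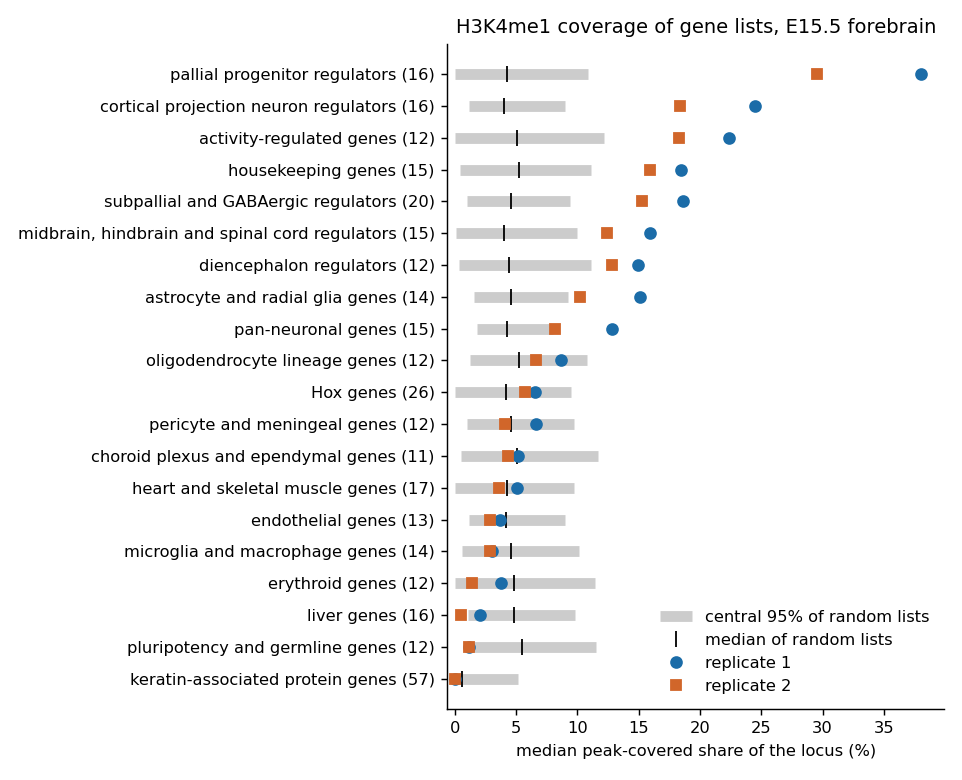
Median peak-covered share of the locus (x axis, %) for the 20 lists of up to 57 genes (y axis, number of genes in brackets), as points for replicate 1 (circles) and replicate 2 (squares) over the central 95% (grey bars) and the median (black ticks) of length-matched random lists. Pallial progenitor regulators lie farthest to the right at a mean of 33.8%, and liver, pluripotency and germline, and keratin-associated protein genes lie near 0.

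The longest H3K4me1 domains, as peaks joined over short gaps, lay at Gse1, Bcl11b and the host gene of a neural microRNA. When peaks of the replicated list were joined over gaps of 1 kb or less, the longest domain spanned 54.2 kb on chromosome 8, from 120489973 to 120544137 (mm10), inside Gse1 and the overlapping gene model Gm20388. The second spanned 44.0 kb on chromosome 12, from 107956998 to 108000961, inside Bcl11b. The third spanned 42.8 kb on chromosome 7, from 79508502 to 79551278, over the noncoding host gene Mir9-3hg of the neural microRNA miR-9, with no coding gene in it. The next were 40.6 kb in Zmiz1, 39.8 kb at Foxo6, a forkhead gene, 37.3 kb in Coro2b and 35.8 kb in Lrp8, a Reelin receptor gene. Pmepa1 and Dab2ip each held a domain of 35.3 kb, and Nfib held the last of the 10, of 34.6 kb. In each of the 10, at least 78.8% of the domain was covered by replicate 1 and at least 58.2% by replicate 2. The rank depended on the joining: with no joining the longest interval was a single peak of 20.5 kb in an intron of Nfix, and with gaps of up to 3 kb the longest domain was 96.0 kb. Of the 10 longest, 4 without joining and 3 with gaps of up to 3 kb overlapped the 10 described here.

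Ranked by covered bases in the less covered replicate, the leading loci included Auts2, Gse1 and Msi2. Auts2, a neurodevelopmental gene on chromosome 5, held 341 kb ± 66.3 of covered sequence, Gse1 195 kb ± 12.9, Msi2, an RNA-binding protein of neural progenitors, 177 kb ± 31.6, and the homeobox gene Pbx1 140 kb ± 20.3. Tenm4 held 153 kb ± 40.6, Ttc28 142 kb ± 26.6, Nfib 139 kb ± 31.4, the E-protein gene Tcf4 139 kb ± 31.5, Celf2 134 kb ± 48.9 and Arid1b 117 kb ± 25.7. Bach2, Nfia and Foxn3 held between 102 kb and 111 kb. The list of 15 also held Gm20388 with 588 kb ± 83.2 and Fgfr2 with 279 kb ± 55.6, whose annotated spans run over neighbouring genes for 4455 kb and 2981 kb including the flanks. None of the 15 were among the 15 loci with the highest covered share, where G430095P16Rik, which lies inside Nfix and shares its marked sequence, stood at 75.5% ± 3.34, Nfix at 67.3% ± 7.71 and Foxo6 at 66.3% ± 6.10.

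At CpG-rich promoters H3K4me1 lay beside the start site more often than on it. At 9723 CpG-rich promoters, 12.4% ± 1.29 (SD, n = 2) of start sites were themselves inside a peak, against 45.4% ± 7.24 at 600 bp upstream and 63.7% ± 5.10 at 1100 bp downstream. The rise from the start site to 1100 bp downstream was 51.2 percentage points ± 3.80, larger than the spread between replicates. At 12181 CpG-poor promoters the profile had no such dip, with 15.1% ± 1.89 at the start site, 15.6% ± 2.64 at 200 bp upstream and 16.6% ± 2.04 at 600 bp downstream. Over the genome, 21.4% ± 1.82 of covered bases lay within 1 kb of a start site, which was 3.36 ± 0.276 times the level of shifted lists. Introns held 51.6% ± 0.996, or 1.28 ± 0.0256 times that level, exons 4.50% ± 0.143, and intergenic sequence 22.6% ± 0.966, or 0.453 ± 0.0189 times. Of peak centres, 81.8% ± 1.87 lay over 1 kb from the nearest start site, and the median distance was 7874 bp ± 973.

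**Figure D2:**
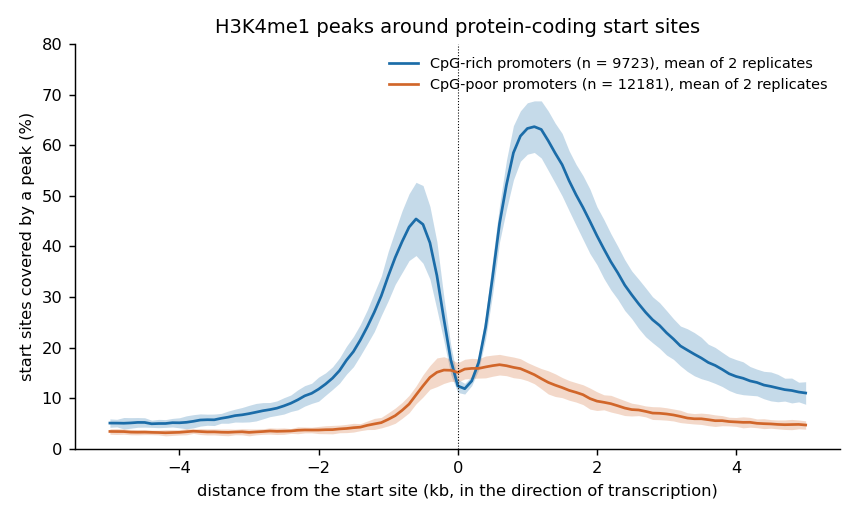
Share of protein-coding start sites covered by a peak (y axis, %) at each position from 5 kb upstream to 5 kb downstream (x axis, kb), for CpG-rich and CpG-poor promoters. Lines are means of the 2 replicates and bands are 1 SD. CpG-rich promoters show 2 flanking maxima, 45.4% upstream and 63.7% downstream, around a minimum near the start site.

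Distal peaks, those over 1 kb from a start site, stood out most from their flanks in the RFX motif and the nuclear factor I pair. The RFX motif is bound by regulatory factor X proteins of ciliated and neural cells. It was 8.51 ± 0.491 times as dense in peaks as in flanking windows of equal length. The paired half-site of nuclear factor I was 5.18 ± 0.414 times as dense. Rearranged versions of the same consensus had medians of 1.28 and 1.22. The highest RFX rearrangement gave 10.5 in replicate 1 and 11.2 in replicate 2, above the motif itself at 8.86 and 8.16. The highest rearrangement of the pair gave 2.04 and 2.18. Both motifs were rare, at 0.00536 and 0.00599 matches per kb of peak. The E-box bound by ASCL1 was 1.93 ± 0.0483 times as dense, the single nuclear factor I half-site 1.51 ± 0.00771 times, the POU octamer 1.45 ± 0.0327 times, the E-box of the NEUROG and NEUROD kind 1.25 ± 0.0113 times, MEF2 1.20 ± 0.0254 times and the homeodomain core TAATTA 1.11 ± 0.0191 times. Relative to rearranged medians, the POU octamer stood at 1.77 times, TAATTA at 1.72, MEF2 at 1.64 and the ASCL1 E-box at 1.53. The single half-site stood at 1.48 and the E-box of the NEUROG and NEUROD kind at 1.20. These 8 motifs of 18 lay above the central 95% of rearrangements in both replicates, although TAATTA had only 13 rearrangements. The E-box of the NEUROG and NEUROD kind fell inside that range in replicate 2, at percentile 96.5, with flanks that started 10 kb from the peak, and in both replicates with peaks of a -log10 q of at least 5.

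The remaining motifs lay within the range of their rearrangements in at least 1 replicate. Motifs of factors of other tissues gave ratios of 0.877 ± 0.0165 for GATA, 0.867 ± 0.138 for HNF1 and 1.62 ± 0.0898 for CEBP, with rearranged medians of 0.895, 0.551 and 1.25. HNF1 lay at percentile 98.0 in replicate 1 and 88.0 in replicate 2. AP-1 gave 0.981 ± 0.00805, SOX 1.02 ± 0.0113, T-box 1.05 ± 0.000820 and TEAD 1.08 ± 0.0131. ETS gave 1.05 ± 0.00161, the nuclear receptor repeat of the COUP kind 0.988 ± 0.0809 and CTCF 1.49 ± 0.305. Their rearranged medians were, in the same order, 0.955, 0.964, 0.996, 0.923, 1.44, 1.05 and 1.52. ETS lay at percentile 2.5 of its rearrangements in replicate 1 and 4 in replicate 2. Peaks had a higher GC content than flanks, 47.5% against 44.3% in replicate 1 and 48.4% against 44.8% in replicate 2. Windows were not matched on it. Peaks were filtered on distance from a start site, and flanks were not.

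**Figure D3:**
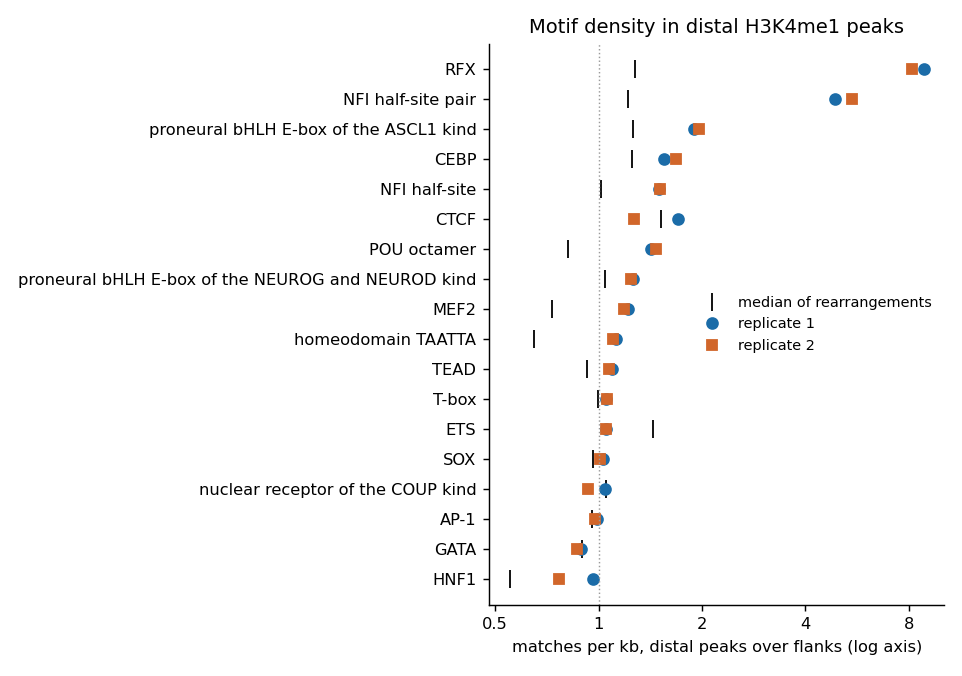
Motif matches per kb in distal peaks divided by matches per kb in flanking windows (x axis, log scale) for 18 motifs (y axis), with circles for replicate 1, squares for replicate 2 and black ticks for the median of rearranged consensus sequences. RFX and the nuclear factor I pair lie farthest right, at means of 8.51 and 5.18. GATA, HNF1 and AP-1 lie below 1 in both replicates, with HNF1 above the median of its rearrangements.

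Nearly all of the strongest peaks of each replicate overlapped a peak of the other. The replicates differed in how much sequence was called, also among peaks with a -log10 q of at least 5. Peaks covered 109 Mb in replicate 1, or 4.12% of the sequenced genome, and 77.8 Mb in replicate 2, or 2.94%, with a mean of 93.4 Mb ± 22.0 (SD, n = 2). Of these, 63.7 Mb were shared, a Jaccard index of 51.8% of the bases covered in either list against 1.97% for shifted lists. Of replicate 1 peaks, 60.5% (95% Wilson interval 60.3 to 60.7) overlapped a replicate 2 peak by 1 bp or more, and of replicate 2 peaks 83.6% (83.4 to 83.7) overlapped a replicate 1 peak. In the strongest decile of each list by the authors' score, 99.6% of replicate 1 peaks and 99.9% of replicate 2 peaks were found in the other list. In the weakest decile the shares were 26.5% and 65.9%. Neighbouring peaks are not independent, so these intervals cover counting error only. With a -log10 q of at least 5 the mean covered length was 55.1 Mb. At that limit 75020 peaks remained in replicate 1 and 46439 in replicate 2, and the distal ones covered 53212 kb and 29303 kb. Requiring overlap of 50% of the peak left 17.3% of the weakest decile of replicate 1 found.

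**Figure D4:**
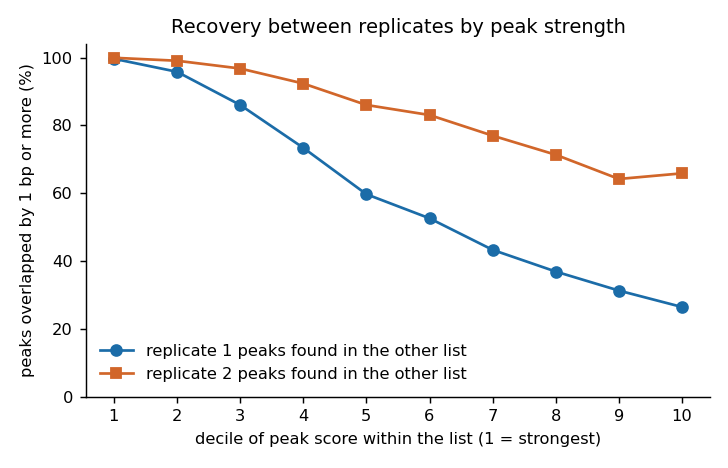
Share of peaks overlapped by 1 bp or more by the other replicate (y axis, %) for each decile of the list by the authors' score (x axis, 1 is the strongest), with circles for replicate 1 peaks and squares for replicate 2 peaks. Replicate 1 falls from 99.6% to 26.5%, and replicate 2 from 99.9% to 65.9%.

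Coverage was higher in replicate 1 at most loci. Among 10469 coding loci of at least 20 kb with a mean share of at least 5%, 9686 were covered more in replicate 1 and 780 more in replicate 2, with a median difference of 2.58 percentage points. The 5 largest differences in percentage points were these. The potassium channel gene Kcna3 was covered over 41.2% in replicate 1 and 24.2% in replicate 2. In the same order, Neurod2 was covered over 67.0% and 50.2%, and Emx2 over 51.1% and 34.5%. The growth cone gene Basp1 was covered over 58.8% and 42.4%, and Pou3f3 over 49.1% and 33.3%. Over the genome, replicate 1 covered 1.40 times the length of replicate 2, so highly covered loci can differ by more points. The largest difference in the other direction was at Tmem249, covered over 26.2% in replicate 1 and 32.2% in replicate 2; it was chosen after its values were seen.

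All 127548 peaks of the replicated list were intervals of the pooled list. Each of the 104228 pooled peaks with an overlap of at least 50%, of either interval, in both replicate lists was in it, and these made up 81.7% of the replicated list. The other 23320 peaks, with a median width of 336 bp, were in the list without that overlap, and 18328 peaks of the list touched no replicate 2 peak at all, while 5303 touched no replicate 1 peak. Pooled peaks left out of the replicated list had a median width of 222 bp, against 583 bp for those in it.

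Chromosome X had the lowest covered share apart from chromosome Y. Peaks covered 0.451% ± 0.166 of it, which was 0.114 ± 0.0151 times the median autosome at 3.88% ± 0.961. Autosomes ranged from 2.89% ± 0.729 on chromosome 14 to 5.78% ± 1.19 on chromosome 11. Chromosome Y held 1 peak in each replicate and consists of 96.3% repeats. Of the 8 list genes on chromosome X, Arx, a homeobox gene of GABAergic neurons, was covered over 16.4% ± 7.05 and Dcx, a gene of migrating neurons, over 13.5% ± 5.82, whereas Pgk1 stood at 7.20% ± 1.10, Syp at 5.93% ± 0.760 and Hprt at 0.878% ± 0.354, and Plp1, Gata1 and Alas2 held no peak. With a -log10 q of at least 5 the ratio of chromosome X to the median autosome was 0.0585.

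**Figure D5:**
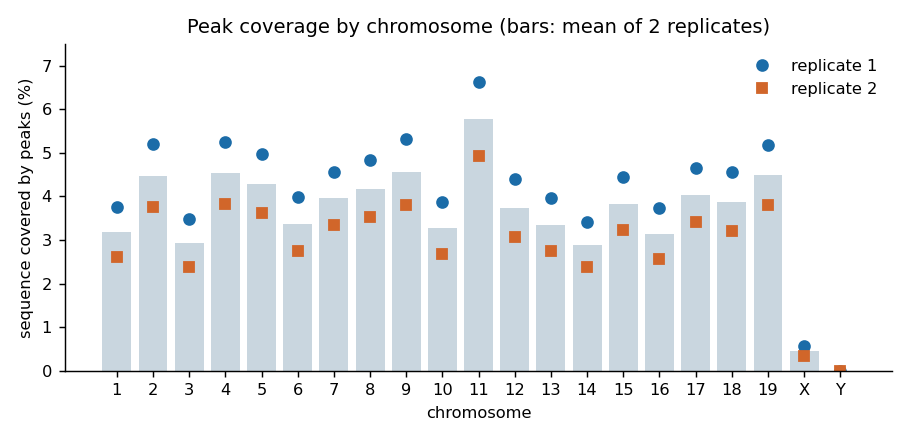
Share of sequenced bases covered by peaks (y axis, %) on each chromosome (x axis), with bars for the mean of the 2 replicates, circles for replicate 1 and squares for replicate 2. Chromosome 11 is highest at a mean of 5.78% and chromosome X stands at 0.451%, below all autosomes.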

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

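The tests of the difference between the replicates and those of gene density and repeats on chromosome X were chosen only after the result was seen.

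A few peaks lay on contigs, which were left out of covered lengths and of the gene, location, motif and chromosome comparisons. In replicate 1, 5 peaks lay on an unlocalized contig of chromosome X, and replicate 2 had 1 there. Replicate 1 also had 1 peak on an unplaced contig, and replicate 2 had 1 and the pooled list 2 on an unlocalized contig of chromosome 4. Of the pooled peaks, 19075, or 9.85%, overlapped no peak of either replicate.

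Replicate 2 covered less sequence than replicate 1, by a ratio of 1.40 in covered length. Strongly marked elements called in only 1 of the 2 pools are argued against. At most 0.358% of the strongest decile of either list was missing from the other at 1 bp of overlap. When 50% of the peak had to be overlapped, 96.9% and 99.8% of these deciles were still found. The other list was searched whole, with its weak peaks. Elements strong in 1 pool and weak in the other were therefore not told apart from elements strong in both. Lower power in replicate 2 may account for the difference, but recovery by peak strength cannot decide it. Of the weakest decile of replicate 1, 26.5% was found in replicate 2, and of that of replicate 2, 65.9% in replicate 1. False calls among the weak peaks of these permissive lists would also lower recovery. Among peaks of up to 400 bp with a fold between 2.9 and 3.1, the median -log10 p was 5.53 in replicate 1 and 5.04 in replicate 2. The control files behind the lists differ exactly as the replicates do, so their effect cannot be told apart from that of the replicate. A real difference between the pools stays open, in the strength of shared elements or in marked sequence below the strongest deciles. No biological explanation was tested, since the series has 1 group.

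Chromosome X stood far below the autosomes in covered share. Gene density is argued against as the whole cause, since chromosome X had 0.777 kb of covered sequence per coding gene, 0.280 times the lowest autosome. Repeats are argued against in the same way: of the sequence outside repeats, chromosome X was covered over 0.847%, 0.191 times the lowest autosome. A lower signal on chromosome X, as its lower dose in pools with males or an inactive copy in females would give, may account for part of the pattern: chromosome X held 0.114% of the strongest decile of replicate 1 peaks (95% exact interval 0.0716 to 0.173) against 1.76% of the weakest decile (1.58 to 1.95), and 0.100% against 1.14% in replicate 2. Any cause that weakens the mark on chromosome X predicts the same values, and no biological explanation was tested, since the pools mix the sexes.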

How the results depend on the processing

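Matching on promoter CpG class was the only alternative chosen after the data were seen. The series holds lists of peaks without read depth, so the power of each list is unknown, and 2 replicates give an SD with little precision. No paired analysis between groups was possible because the series has 1 group. With a -log10 q of at least 5, the mean covered length fell to 55.1 Mb, the Jaccard index to 47.6%, the share of replicate 1 peaks found to 51.1% and the CpG-rich rise to 46.0 points, while the share of replicate 2 peaks found was 88.6%, the start site ratio 4.07 and the chromosome X ratio 0.0585. Fewer peaks remain by construction. With equal numbers of top-ranked peaks the Jaccard index was 53.5% and the shares found 67.1% and 78.8%. Requiring overlap of 50% of a peak gave 47.7% and 76.8%, with 96.9% and 99.8% of the strongest deciles and 17.3% and 54.6% of the weakest found. Overlap of 1 bp in both replicates was met by 82.2% of the replicated list. The start site ratio was 2.59 with a class of 2.5 kb. The longest domain was 20.5 kb without joining and 96.0 kb over gaps of 3 kb, and 0 of the 15 most covered loci remained when ranked by covered share. Above the central 95% of random lists lay 5 lists with 50 kb on each side, and below it 1 list with promoter class matched. Beyond what these constructions fix, the cause was not tested. Without each replicate in turn, covered length ranged from 77.8 to 109 Mb, the start site ratio from 3.16 to 3.55, the CpG-rich rise from 48.5 to 53.9 points, the chromosome X ratio from 0.103 to 0.125, the lists below the range from 2 to 3, and the motifs above it from 8 to 9. Over all alternatives, percentiles of single lists stayed inside or outside the central range in 160 cases, moved inside in 10 and outside in 6. Single motifs did so in 69, 2 and 1 cases. No list or motif reversed, counting only cases with a value outside the range. Lists inside the range did cross the middle. With promoter class matched, Hox genes moved from percentile 77.1 to 10.9, microglia and macrophage genes from 23.2 to 69.7 and erythroid genes from 28.4 to 69.0.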

Other observations

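The values by symbol family and by promoter class on chromosome X were chosen only after the data were seen, as was the matching on promoter class, whose test and that of neighbouring genes were fixed before their own results were seen.

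Histone genes stood out among gene families that were not part of the fixed lists. Of 139 families of at least 15 coding genes that share a symbol stem, the 67 histone genes had the highest median covered share. It was 22.8% ± 4.43 (SD of the replicate medians, n = 2), against 0.787% for random genes of the same length. The median of all coding genes, at 4.66%, lay above that of these random short genes and below that of the histone genes. Random lists for families were matched on length only, not on promoter CpG class. Hist1h3d was covered over 37.4% ± 4.11 and Hist1h4d over 35.7% ± 4.34. Sox genes followed with 16.7% ± 2.16 over 19 genes, where Sox8 at 54.2% ± 4.34 and Sox1 at 51.9% ± 3.42 joined Sox2, and 6 of the 19 were also in the fixed lists. Semaphorin genes, which guide growing axons, had a median of 12.7% ± 1.54 over 20 genes, led by Sema4b at 31.8% ± 4.76 and Sema3f at 31.3% ± 2.47. Wnt genes had a median of 11.2% ± 2.45 over 19 genes. Other families stood as high or higher than the Wnt genes: 13.6% ± 1.59 for the F-box genes of the Fbxl stem, 12.3% ± 1.16 for Klf genes, 12.3% ± 2.18 for genes of the Bcl stem and 12.2% ± 2.06 for the ribosomal protein genes of the Rpl stem. Above the central 95% of random lists lay 31 families and below it 26. Among the latter were the cytochrome P450 genes of the Cyp stem, where 56 of 100 genes held no peak in either replicate, and the glucuronosyltransferase genes of the Ugt stem, where 12 of 22 held none. Neighbouring genes share windows, which holds above all for the clustered histone genes.

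Among loci of at least 20 kb on chromosome X, Efnb1, an ephrin ligand gene, had the highest covered share at 36.6% ± 4.43. Bcor, a corepressor gene, followed at 23.9% ± 3.78 and Pja1 at 21.1% ± 5.75. The 226 genes of chromosome X with CpG-rich promoters had a median covered share of 1.81%, against 7.87% for 9496 autosomal ones, and 5.75% of them held no peak, against 0.874%.

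Regulators of midbrain, hindbrain and spinal cord were covered more than random genes in a forebrain dissection. Marked neighbouring genes inside the window are argued against: the 11 members with no other coding gene in their window had a median of 13.5% and stood at percentile 99.99 among random genes of the same kind. The promoter class stays open and may account for much of the pattern, since 12 of the 15 members have CpG-rich promoters and the list stood at percentile 92.4 among random lists matched on length and class, whose median was 9.07%. A percentile inside the range does not show that no difference is left. No biological explanation was tested, since the series holds no other tissue.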
